A study of Homo sapiens with 4 samples.

How the data were processed

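Gene expression was measured on 4 Affymetrix arrays, 1 per RNA sample, in cells labelled HepG2, a human hepatocellular carcinoma line. Per the labels' protocols, all cells were kept in DMEM with 10% serum and 40 mM glucose for 48 h, siRNA was given after the first 24 h, RNA was extracted with TRIzol and the target was labelled with biotin. The labels give 2 arrays of cells that received a non-targeting control siRNA and 2 arrays of cells that received TCF19 siRNA, and they call the arrays of a group biological replicates, without saying whether they came from separate cultures or days. The p-values therefore measure only the spread between these samples, which can be technical. The number of arrays, 2 per group, limits the precision.

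The deposited values are log2 signals made by the authors with RMA (robust multi-array average, which corrects the background, normalises the arrays to each other and summarises the probes of a probe set), per the submitters' processing notes. The software version and the genome build were not given in the sources used here. All 49395 probe sets had a median over the 4 arrays within 1e-05 of 0, so the deposited values were centred per probe set. They hold differences between arrays and no level, and neither the brightness of a probe set nor its distance from background can be read from them. The log2 scale was taken from RMA, which returns log2 values, because a centred table does not show its own log base. The direction follows from the array columns, which carry the samples' names. The median over all probe sets was 0.02 in control siRNA replicate 1, 0.02 in control siRNA replicate 2, -0.0018 in TCF19 siRNA replicate 1 and -0.04 in TCF19 siRNA replicate 2.

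Probe sets were named through the array's annotation table, which can be old, and symbols were updated by Entrez number through a RefSeq gene table of the assembly GRCh38.p14, which changed 0 symbols. Of the 49395 probe sets, 102 were the manufacturer's control probe sets, 44988 had 1 gene symbol, 1832 had several and 2473 had none. Only probe sets with 1 symbol were used for genes, and the mean of all probe sets of a gene gave 18132 genes, 6398 of them with a single probe set. The RefSeq table also gave the order of neighbouring genes.

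The comparison was TCF19 siRNA minus control siRNA, fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 and tested two-sided, with Benjamini-Hochberg adjustment over the 18132 genes and a threshold of 0.05. There were 2 residual degrees of freedom per gene and 2.78 prior degrees of freedom. A log2 fold change is given as mean ± SE from this fit. The design fixed before the data were examined had an intensity trend in eBayes and took the brightest probe set per gene. Both need a level, which centred values do not hold, so the fit was made without the trend and with the mean over probe sets. The trend as first written is reported among the alternatives, where its covariate is the mean of the centred values. Gene lists were tested with camera (limma) at its preset inter-gene correlation of 0.01 and adjusted over 41 lists. With the correlation estimated from the data, which rests on the same 2 residual degrees of freedom, 0 of the 41 lists passed. The 41 lists, 35 of pathways, complexes and neighbouring genes and 6 of markers of other cell types, were fixed before the data were examined. They hold 1226 entries, of which 1138 were measured. The result of 1 list is not used here.

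The genes named were chosen by a rule that was also fixed beforehand: TCF19 and the other candidate genes, the 12 largest rises and 12 largest falls among genes that passed the threshold without overlap between the groups' arrays, and up to 4 members with the smallest p in the direction of each list that passed or had at least 3 members past the threshold. Genes named outside it are said to be so. A description without a test counted the genes whose group means were at least 1.5-fold apart with both arrays of a group above both arrays of the other. The steps were tested on simulated data, with each gene's variance drawn from limma's prior for the real arrays. Genes were simulated independently and with equal variance in both groups. In the real arrays the SD of the difference was 0.51 between the TCF19 siRNA arrays and 0.19 between the controls. The false calls of the simulation therefore need not hold for the real arrays. Among the 18132 genes simulated for TCF19 siRNA minus control siRNA, 0% of 50 genes changed by log2 0.585 were recovered, 30% of 50 changed by 1.00, 84% of 50 changed by 2.00 and 98% of 50 changed by 4.00. Of 112 calls 6 were false, and the 1 shifted gene list was found with 0 others called.

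The pool of control-like RNA in an array was computed gene by gene on the linear scale, and that step too was tested on simulated data. Neighbouring genes were compared with 1000 shuffled gene orders. Alternatives changed the variance model, the array scaling, the probe sets per gene, the threshold and the gene set test, left out each array in turn, or took the replicate number as a block. Filters on dim probe sets, quantile normalisation and cyclic loess were planned and not run, because they need levels. The fits with probe sets of unshared sequence only, with a robust prior and no trend, and with an array left out and the correlation estimated were chosen after seeing the data.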

Results

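The series compared HepG2 cells in which TCF19 was targeted by siRNA with cells given a non-targeting siRNA, both kept in 40 mM glucose. TCF19 encodes a protein with a forkhead-associated domain and a PHD finger, a fold that binds modified histone H3. Each group had 2 arrays, and 18132 genes were measured as log2 signals relative to each probe set's median over the 4 arrays. The question was which transcripts differ when TCF19 is lowered in high glucose. The arrays give relative values only, so no gene is described as expressed or silent. The groups are compared as labelled, and the arrays do not show whether their cells differed in TCF19 siRNA alone.

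TCF19 itself was lower in both TCF19 siRNA arrays. Its relative log2 signal was 0.33 and 0.55 in control siRNA replicates 1 and 2, and -0.46 and -0.33 in TCF19 siRNA replicates 1 and 2. The log2 fold change was -0.84 ± 0.13 (SE, n = 2 against 2 arrays, limma adjusted p = 0.0186), with a 95% interval from -1.17 to -0.50. This is a 1.79-fold difference, with 55.9% of the control signal left, measured by 1 probe set. A total of 1157 genes (6.38%) had a larger mean fall than TCF19, and 669 of them passed the threshold. Without control siRNA replicate 1 the log2 fold change was -0.95 and without control siRNA replicate 2 it was -0.73, and neither passed (adjusted p = 0.139 and 0.153).

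Among the other candidate genes, HDAC1, a histone deacetylase of the NuRD chromatin remodelling complex, and SCO2, an assembly factor of cytochrome c oxidase, rose. HDAC1 had a log2 fold change of 1.11 ± 0.15 (adjusted p = 0.0150) with 2 of its 3 probe sets higher, and SCO2 one of 0.76 ± 0.10 (adjusted p = 0.0150). The 3 candidates that encode enzymes of gluconeogenesis did not pass. PCK1, which encodes phosphoenolpyruvate carboxykinase, had -0.24 ± 0.11 (adjusted p = 0.154), the glucose-6-phosphatase gene G6PC1 -0.38 ± 0.11 (adjusted p = 0.0622) and the fructose-1,6-bisphosphatase gene FBP1 -0.25 ± 0.13 (adjusted p = 0.198). All 3 were below both controls in both TCF19 siRNA arrays, but so were 7726 of all 18132 genes. TIGAR, which lowers the flux through glycolysis, had 0.39 ± 0.13 (adjusted p = 0.0863), and the cell cycle inhibitor gene CDKN1A had -0.60 ± 0.23 (adjusted p = 0.115), with -0.91 in TCF19 siRNA replicate 1 and -0.28 in replicate 2 relative to the control mean. The NuRD members CHD4 and MTA1 had -0.25 and -0.16 and did not pass. In all, 3 of the 10 measured candidates changed, TCF19 included, and 4 did when adjusted over the list alone, the fourth being G6PC1. Without either control array, 0 of the 10 passed.

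**Figure D1:**
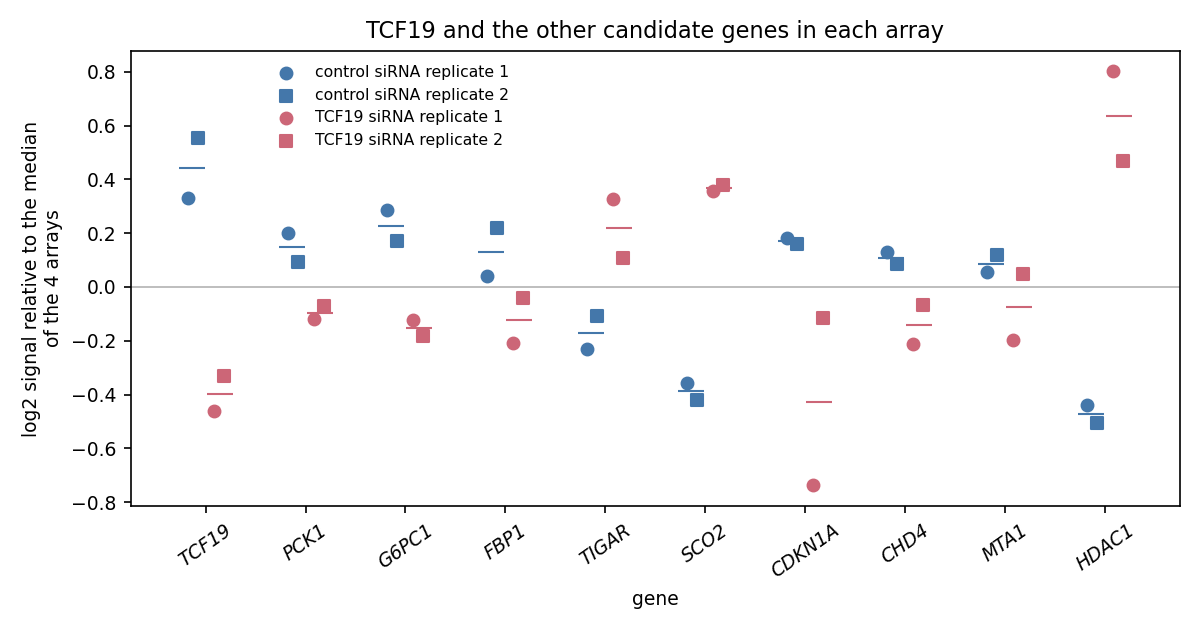
Relative log2 signal (y axis, relative to the median of the 4 arrays) of TCF19 and 9 other candidate genes (x axis) in each array; circles are replicate 1, squares replicate 2, and short lines the group means. TCF19 lies at 0.33 and 0.55 in the control arrays and at -0.46 and -0.33 in the TCF19 siRNA arrays, and CDKN1A differs between the TCF19 siRNA arrays.

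Differences between the groups reached far beyond TCF19. Of 18132 genes, 4379 (24.2%) changed, 2794 of them higher and 1585 lower with TCF19 siRNA, and 1299 of the higher and 486 of the lower genes did so by at least 2-fold. With the arrays shifted to a common median, 3213 genes were higher and 1021 lower. The groups' means were at least 1.5-fold apart without overlap for 4498 genes, 2628 higher and 1870 lower. The arrays of the groups did not overlap for 72.5% of all genes, against 33.3% by chance with 2 against 2 arrays. Here 5427 genes were higher and 7726 lower, so the balance turned to lower. A shift of whole arrays also separates groups in this way, and the median log2 fold change of all genes was -0.09.

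The rise was largest for UCHL1, a neuronal ubiquitin hydrolase (7.74 ± 0.18 on the log2 scale, adjusted p = 0.0044), followed by MAGEA4, a gene otherwise known from testis and tumours (7.06 ± 0.23), COXFA4L3 (6.71 ± 0.22), PLBD1 (5.84 ± 0.18) and GTSF1 (5.72 ± 0.21). SPP1, which encodes the secreted protein osteopontin, rose by 5.71 ± 0.20, with all 6 probe sets higher. The others of the 12 largest were HORMAD1 (5.65), the scaffold gene AKAP12 (5.47), NRIP3 (5.42), MAGEA12 (5.08), PNMA8A (5.06) and the calponin gene CNN3 (5.05). Their adjusted p values lay between 0.0044 and 0.0096.

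The 12 largest falls that passed were smaller, between -2.70 and -2.30, with adjusted p values from 0.0331 to 0.0448. They were SAMD9, an interferon-inducible gene (-2.70 ± 0.63), the fatty acid binding protein gene FABP3 (-2.70 ± 0.64), the nuclear receptor gene RORA (-2.64 ± 0.64), the growth factor gene NRG4 (-2.64 ± 0.56), DNAJC12 (-2.61), NCCRP1 (-2.56), CSRNP1 (-2.54), MYZAP (-2.39), the desmosomal cadherin gene DSG2 (-2.34), TNFAIP6 (-2.32), SRGN (-2.30) and NFIL3 (-2.30). Larger mean falls existed and did not pass. All 33 genes with a mean rise of at least 16-fold passed, and 0 of the 25 genes with a mean fall of at least 16-fold did. Among the latter, named here after their values were seen, the matrix proteoglycan gene LUM was at -9.17 in TCF19 siRNA replicate 1 and at -1.30 in replicate 2 relative to the control mean, AKR1C1 at -8.74 and -1.42, the cytokine gene IL18 at -7.13 and -2.17, and the insulin-like growth factor binding protein gene IGFBP1 at -7.05 and -1.53.

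The TCF19 siRNA arrays were thus unlike each other. The SD of the difference between them over genes was 0.51 on the log2 scale, against 0.19 between the control arrays, and 497 genes were at least 2-fold apart between them against 11 between the controls. Between groups, 2993 and 2964 genes were at least 2-fold apart for TCF19 siRNA replicate 1 and 1507 and 1470 for replicate 2. The first principal component held 89.7% of the variance and placed TCF19 siRNA replicate 2 (23.7) between the controls (-51.3 and -50.8) and TCF19 siRNA replicate 1 (78.5). The 40 genes more than 64-fold lower in replicate 1 had a median log2 difference of -6.87 there and of -1.22 in replicate 2, while the 41 genes at least 16-fold higher had medians of 4.85 and 4.27.

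The counts of changed genes depend on single arrays. Without TCF19 siRNA replicate 1, limma called 4683 genes, 3799 of them among the 4379, and without TCF19 siRNA replicate 2 it called 6663. Without control siRNA replicate 1 or 2, it called 0 genes, with 4190 and 4279 at an unadjusted p under 0.05. In those fits the lone control array is assumed to vary like the TCF19 siRNA arrays.

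**Figure D2:**
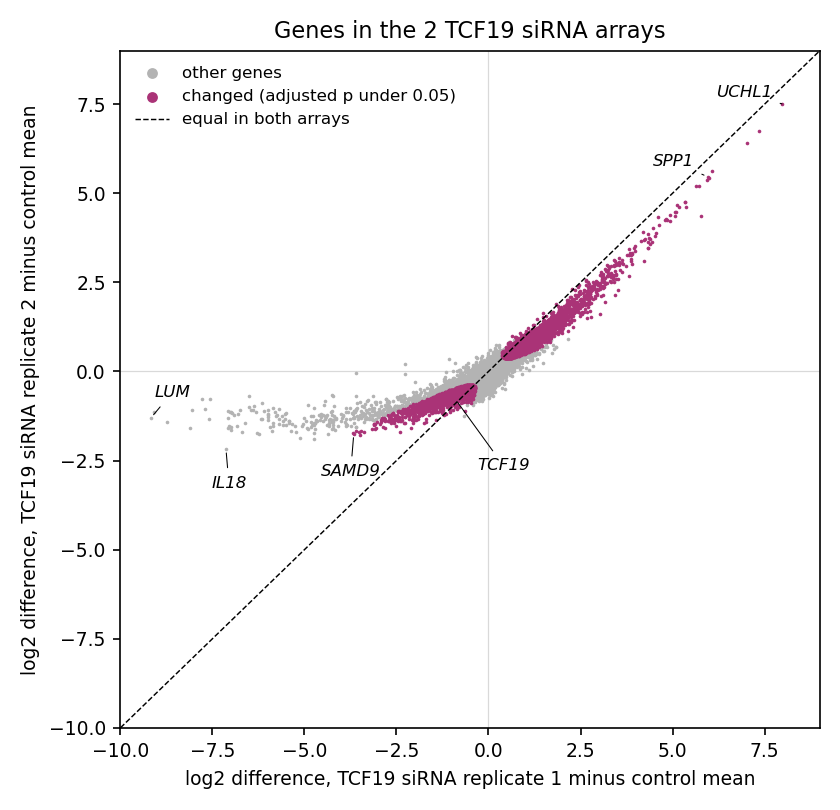
Each point is a gene, with its log2 difference from the control mean in TCF19 siRNA replicate 1 (x axis) and replicate 2 (y axis); the 4379 changed genes are coloured and the dashed line marks equal values. Rises lie close to the line (UCHL1 at 7.97 and 7.51), while deep falls in replicate 1 level off in replicate 2 (LUM at -9.17 and -1.30).

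Lists of genes of the cell division cycle were higher by camera. Of 63 genes of the G2/M and mitosis list, 36 rose and 3 fell, with a mean log2 fold change of 0.77 ± 0.09 (SE across genes, camera adjusted p = 4.47e-12). Among them were HMMR (2.82 ± 0.20), the kinetochore gene NDC80 (2.16 ± 0.20) and the chromosomal passenger genes CDCA8 (2.33 ± 0.17) and AURKB (1.45 ± 0.13). Of 55 genes of G1/S and DNA replication, 23 rose and 1 fell, with a mean of 0.55 ± 0.12 (camera adjusted p = 3.54e-06). These included POLE2, a subunit of DNA polymerase epsilon (3.30 ± 0.21), the cohesion factor gene DSCC1 (2.84 ± 0.23), the primase gene PRIM1 (1.82 ± 0.16) and the cyclin D1 gene CCND1 (1.54 ± 0.12). Adjusted over the list alone, 43 and 36 members changed. The list means were 0.90 and 0.60 in TCF19 siRNA replicate 1 and 0.65 and 0.49 in replicate 2. Neither list passed with an estimated correlation (adjusted p = 0.593 for both).

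Genes of mitochondrial and cytosolic ribosomes and of RNA interference also passed as lists. Of 50 mitochondrial ribosomal protein genes, 18 rose and 1 fell (mean 0.38 ± 0.08, camera adjusted p = 0.000124, 22 changed when adjusted over the list alone), with MRPS28 at 1.93 ± 0.16, MRPS12 at 1.91 ± 0.15, MRPS23 at 1.41 ± 0.12 and MRPL28 at 1.04 ± 0.12. Of 48 cytosolic ribosomal protein genes, 6 rose and 1 fell, with a small mean of 0.14 ± 0.05 (camera adjusted p = 0.0417, 6 adjusted over the list alone). That is 14.6% of the list, against 24.2% of all genes. RPS14 rose by 1.19, RPS16 by 0.67 and RPS7 by 0.53. RPS23 had 0.88, but only 1 of its 3 probe sets was higher, and it was at -0.09 with the probe sets of shared sequence left out, an alternative chosen after seeing the data. Of 15 RNA interference genes, 5 rose and 2 fell (mean 0.31 ± 0.13, camera adjusted p = 0.0276, 9 adjusted over the list alone). XPO5, which exports microRNA precursors, had 0.88 ± 0.11, TSN 0.98 ± 0.16, DICER1, which cuts them, 0.93 ± 0.20, and the Argonaute gene AGO2 0.42 ± 0.10. The means of these 3 lists were 0.43, 0.16 and 0.38 in TCF19 siRNA replicate 1 and 0.34, 0.11 and 0.23 in replicate 2. None of them passed with an estimated correlation (adjusted p = 0.593). The call of the cytosolic ribosomal list ended without control siRNA replicate 1, control siRNA replicate 2 or TCF19 siRNA replicate 2 (adjusted p = 0.0544, 0.113 and 0.0528), and that of the RNA interference list without control siRNA replicate 1 (adjusted p = 0.0544).

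The list of targets of hypoxia-inducible factor was lower by camera. Of 27 measured, 14 fell, 1 rose and 12 did not pass, and 26 changed when adjusted over the list alone, with a mean of -1.42 ± 0.17 (camera adjusted p = 3.54e-06). BNIP3, a mitophagy receptor gene, had -1.31 ± 0.22, the oxidoreductase gene ERO1A -1.19 ± 0.21, INSIG2 -0.77 ± 0.12 and the histone demethylase gene KDM3A -0.70 ± 0.11. The list's mean was -1.98 in TCF19 siRNA replicate 1 and -0.85 in replicate 2. Of 25 glycolysis genes, 4 fell and 1 rose, 0 adjusted over the list alone (mean -0.65 ± 0.17, camera adjusted p = 0.0209). That is 20% of the list, against 24.2% of all genes. The falls were in the hexokinase-like gene HKDC1 (-2.08 ± 0.49), the muscle phosphofructokinase gene PFKM (-0.65 ± 0.16) and the bifunctional regulators PFKFB3 (-1.52 ± 0.36) and PFKFB2 (-0.70 ± 0.16). The mean was -0.93 in TCF19 siRNA replicate 1 and -0.37 in replicate 2. Neither list passed with an estimated correlation (adjusted p = 0.593).

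Of 17 gluconeogenesis genes, 4 fell and 1 rose, and 8 changed when adjusted over the list alone (mean -0.41 ± 0.13, camera adjusted p = 0.0276). The falls were in regulators and in the first enzyme of the pathway from pyruvate: the coactivator gene PPARGC1A (-1.31 ± 0.21), the glucocorticoid receptor gene NR3C1 (-1.22 ± 0.21), the forkhead factor gene FOXO1 (-0.78 ± 0.11) and the pyruvate carboxylase gene PC (-1.16 ± 0.21). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, was the member that rose (0.85), and is named after its value was seen. The list mean was -0.48 in TCF19 siRNA replicate 1 and -0.33 in replicate 2. The list did not pass with an estimated correlation (adjusted p = 0.593), nor without control siRNA replicate 2 (adjusted p = 0.0627).

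Of the lists of interferon, inflammatory and stress genes, 4 were lower by camera, with most members not passing. Of 39 interferon response genes, 10 fell and 2 rose, 14 adjusted over the list alone (mean -0.94 ± 0.17, camera adjusted p = 7.33e-05), with ISG20 at -1.49 ± 0.22, the transcription factor gene IRF9 at -1.03 ± 0.20, CXCL10 at -0.84 ± 0.14 and IFI44 at -1.40 ± 0.26, although 2 of the 6 probe sets of IFI44 were higher. Of 28 genes of the NF-kB response, 7 fell and 0 rose, 13 adjusted over the list alone (mean -1.14 ± 0.21, camera adjusted p = 0.000595), among them the chemokine gene CCL20 (-2.20 ± 0.43), MAP3K8 (-1.16 ± 0.19), the cytokine gene IL1B (-1.03 ± 0.11) and IRAK2 (-0.95 ± 0.12). Of 30 genes of the unfolded protein response, 10 fell and 1 rose, 13 adjusted over the list alone (mean -0.41 ± 0.08, camera adjusted p = 0.000323), among them EIF2AK3, the sensor kinase PERK (-1.67 ± 0.32), SELENOK (-0.94), DNAJC3 (-0.89) and EDEM1 (-0.81). Of 35 NRF2 and oxidative stress genes, 9 fell and 1 rose, 11 adjusted over the list alone (mean -0.83 ± 0.21, camera adjusted p = 0.0209), among them the aldo-keto reductase gene AKR1B10 (-1.35 ± 0.16), the catalase gene CAT (-1.03 ± 0.18), the metallothionein gene MT1F (-0.73) and the cystine transporter gene SLC7A11 (-0.63). The means of these 4 lists were -1.33, -1.68, -0.53 and -1.25 in TCF19 siRNA replicate 1 and -0.55, -0.61, -0.30 and -0.41 in replicate 2. None of them passed with an estimated correlation (adjusted p = 0.593).

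Among lists of hepatocyte function, acute phase proteins and drug and bile acid metabolism passed. Of 26 acute phase genes, 3 fell, the receptor genes IL6ST (-0.66 ± 0.13) and IL6R (-0.48 ± 0.11) and the C-reactive protein gene CRP (-0.51 ± 0.12), and 0 rose (mean -0.55 ± 0.18, camera adjusted p = 0.0276). Of 36 genes of drug and bile acid metabolism, 2 fell, the aryl hydrocarbon receptor gene AHR (-1.55 ± 0.35) and the fetal cytochrome gene CYP3A7 (-0.84 ± 0.15), and 0 rose (mean -0.41 ± 0.11, median -0.21, camera adjusted p = 0.0209). The median of the latter lay near the -0.22 of the hair keratin-associated KRTAP genes, which camera also called lower (adjusted p = 0.0166). Of the members of these lists, 11.5% and 5.56% changed, against 24.2% of all genes. Adjusted over the list alone, 0 members of either changed. The means were -0.76 and -0.50 in TCF19 siRNA replicate 1 and -0.34 and -0.32 in replicate 2. Neither passed with an estimated correlation (adjusted p = 0.593), and the acute phase call ended without control siRNA replicate 2 (adjusted p = 0.173). Coagulation and complement (2 higher and 1 lower of 36, mean -0.32, camera adjusted p = 0.0556), apolipoproteins and lipoprotein export (1 higher and 3 lower of 21, mean -0.25, adjusted p = 0.182) and hepatocyte transcription factors and identity (1 higher and 2 lower of 25, mean -0.43, adjusted p = 0.0812) did not pass. Of these, PROS1 (-0.99), APOM (-1.34), LRP1 (-0.63), FOXA1 (-0.70), CEBPB (-0.82) and SCARB1 fell, and the complement gene C5 (1.61), the clotting factor gene F12 (1.19) and APOC1 (0.56) rose, these 3 named after their values were seen. The higher member of the identity list was SPP1 (5.71). The means of these 3 lists were -0.41, -0.23 and -0.63 in TCF19 siRNA replicate 1 and -0.23, -0.26 and -0.23 in replicate 2. The coagulation list passed without TCF19 siRNA replicate 1 or 2 (adjusted p = 0.0351 and 0.0498), and the identity list without control siRNA replicate 1, TCF19 siRNA replicate 1 or TCF19 siRNA replicate 2 (adjusted p = 0.0140, 0.0351 and 0.0465).

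**Figure D3:**
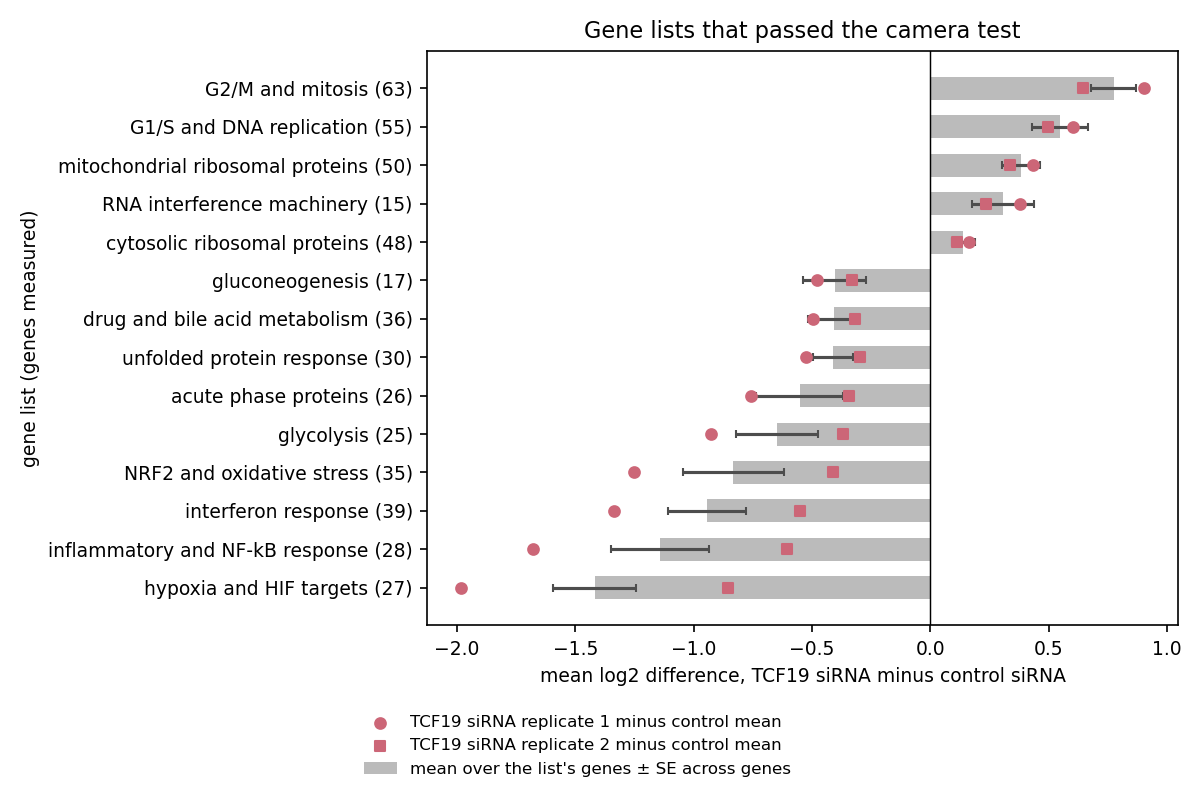
Mean log2 difference between TCF19 siRNA and control siRNA (x axis) of the 14 gene lists that passed camera (y axis, genes measured in parentheses); bars are means over genes with the SE across genes, and circles and squares the means in TCF19 siRNA replicates 1 and 2. The 5 higher and 9 lower lists keep their sign in both arrays, with hypoxia targets at -1.98 and -0.85.

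Nuclear genes of oxidative phosphorylation had 13 higher and 3 lower of 68, 16 adjusted over the list alone (mean 0.07 ± 0.05, camera adjusted p = 0.220), with SCO1 at 1.06, COX6B1 at 0.95, COX4I1 at 0.85 and NDUFAB1 at 0.82. The TCA cycle had 3 higher (SDHD 1.24, MDH2 1.23 and IDH3B 0.71) and 1 lower of 19, with a mean of 0.03 and a median of -0.19 (camera adjusted p = 0.836). The means of the oxidative phosphorylation and TCA cycle lists were 0.06 and 0.0034 in TCF19 siRNA replicate 1 and 0.09 and 0.05 in replicate 2.

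Complexes that act on chromatin also had members on both sides. In the NuRD list, 4 of 16 rose and 2 fell, 8 adjusted over the list alone. Besides HDAC1, the falls in GATAD2B (-0.56 ± 0.10, with 1 of 3 probe sets higher) and CDK2AP1 (-0.49 ± 0.10) stood against a list mean of -0.02 (camera adjusted p = 0.903). Of 28 genes of the H3K4 methylation machinery, 6 rose and 4 fell, 13 adjusted over the list alone (mean 0.02, camera adjusted p = 0.392), with CXXC1 at 1.01, WDR5 at 1.01, PHF13 at 0.60 and KDM5A at 0.50. Of 21 neighbours of TCF19 in the MHC region, 3 rose and 6 fell (mean -0.46, camera adjusted p = 0.345), among them POU5F1 (-2.23 ± 0.44), PSORS1C1 (-1.29), DDX39B (-1.03) and GTF2H4 (-0.58). Histone genes had 1 higher and 1 lower of 14 (mean -0.46, camera adjusted p = 0.138, and 0.0113 without TCF19 siRNA replicate 2), and heat shock proteins 4 higher and 2 lower of 22 (mean -0.01, median 0.01, ranked higher by camera, adjusted p = 0.429), with HSPA8 (1.28), STIP1 (1.22), HSPA4 (0.90) and HSPE1 (0.73) higher. The means of the NuRD, H3K4, MHC region, histone and heat shock lists were -0.04, -0.00077, -0.66, -0.70 and -0.07 in TCF19 siRNA replicate 1 and 0.0092, 0.04, -0.27, -0.21 and 0.05 in replicate 2.

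The remaining metabolic and signalling lists did not pass with all 4 arrays. By ranks, camera called autophagy and lysosome (adjusted p = 0.0401) and epithelial and mesenchymal markers (0.0341) lower. Without TCF19 siRNA replicate 2, cholesterol synthesis (adjusted p = 0.0285), the ATF4 and amino acid response (0.0263), autophagy and lysosome (0.0231) and epithelial and mesenchymal markers (0.00410) passed, the last also without TCF19 siRNA replicate 1 (0.0434). Fatty acid oxidation had 2 higher and 4 lower of 23 (camera adjusted p = 0.435), with falls in PDK4 (-1.36), CPT1A (-0.81), PPARA (-0.58) and HADH (-0.55). Cholesterol synthesis had 1 higher and 3 lower of 19 (adjusted p = 0.0979), with falls in STARD4 (-1.11), MSMO1 (-0.59) and DHCR7 (-0.50). Fatty acid and triglyceride synthesis had 3 higher and 2 lower of 22 (ME1 at -0.77 and ARRDC4 at -0.95, adjusted p = 0.631), glycogen metabolism 3 higher and 3 lower of 19 (PGM1 at -1.32, PYGL at -0.93 and UGP2 at -0.68, adjusted p = 0.220) and the pentose phosphate pathway 1 higher and 0 lower of 8 (mean -0.11, ranked higher by camera, adjusted p = 0.967). The means of these 5 lists were -0.23, -0.48, -0.15, -0.56 and -0.16 in TCF19 siRNA replicate 1 and -0.08, -0.24, -0.04, -0.22 and -0.06 in replicate 2. The ATF4 and amino acid response had 7 higher and 5 lower of 38 (CTH at -1.67 and DDIT3 at -1.22, adjusted p = 0.501), insulin and growth factor signalling 8 higher and 7 lower of 36 (RICTOR at -1.43, MET at -0.81 and EGR1 at -0.80, adjusted p = 0.829), and apoptosis regulators 3 higher and 2 lower of 29 (BCL2A1 at 0.93, FADD at 0.78 and BCL2L1 at 0.47, mean -0.09, ranked higher by camera, adjusted p = 0.967). Autophagy and lysosome had 3 higher and 11 lower of 39 (CTSL at -0.89, CTSB at -0.87, ATG4A at -0.71 and HEXA at -0.71, adjusted p = 0.108), and epithelial and mesenchymal markers 6 higher and 8 lower of 33 (FN1 at -1.06, THBS1 at -1.05, LOXL2 at -0.93 and TGFBR1 at -0.68, adjusted p = 0.0911). Members that went the other way, named after their values were seen, were the asparagine synthetase gene ASNS (1.92), PSAT1 (1.75) and CEBPG (1.19) of the ATF4 list, GYG1 (1.61) and PGM2 (1.31) of glycogen metabolism, CPT2 (1.54) of fatty acid oxidation, DGAT2 (1.12) of triglyceride synthesis, ACAT2 (0.87) of cholesterol synthesis, DUSP6 (3.59) and SPRY2 (2.43) of growth factor signalling, ATG5 (0.94) of autophagy, CCN2 (1.73) and MMP14 (1.38) of the epithelial and mesenchymal list, and CASP2 (-0.80) of apoptosis. The means of the ATF4, insulin, apoptosis, autophagy and epithelial lists were -0.64, -0.53, -0.13, -0.39 and -0.85 in TCF19 siRNA replicate 1 and -0.13, -0.03, -0.05, -0.19 and -0.29 in replicate 2.

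None of the 6 lists of other cell types passed, which does not mean that each member was alike in the groups. Relative to the control mean, the cholangiocyte marker gene KRT7 was at -7.80 in TCF19 siRNA replicate 1 and at -0.77 in replicate 2. Named after its value was seen, KRT7 did not pass (limma adjusted p = 0.219). Fibroblast and stellate cell markers had 0 changed members of 14 (mean -0.71, camera adjusted p = 0.188), although LUM is one of them, and means of -1.07 in TCF19 siRNA replicate 1 and -0.35 in replicate 2. Cholangiocyte markers had 1 higher and 1 lower of 11 (mean -0.83, camera adjusted p = 0.195), with means of -1.36 in TCF19 siRNA replicate 1 and -0.31 in replicate 2, and passed without TCF19 siRNA replicate 2 (adjusted p = 0.0211). Endothelial cell markers had 1 higher and 1 lower of 14 (adjusted p = 0.420), macrophage markers 1 and 1 of 15 (0.449), lymphocyte markers 0 and 1 of 13 (0.186), and squamous and HeLa-type epithelial markers 0 and 0 of 7 (0.602).

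The manufacturer's control probe sets also differed between the groups. The 27 poly-A spike-in probe sets had a median difference of -1.62 in TCF19 siRNA minus control siRNA on the log2 scale and 25 of them were lower in both TCF19 siRNA arrays. The 9 hybridisation controls had a median of -1.03, all lower in both, and the 23 background probe sets -0.12, all lower in both. The ACTB and GAPDH probe sets at the 5' end, which read RNA integrity and labelling when set against those at the 3' end, were 0.68 and 0.22 higher with TCF19 siRNA, while the 3' probe sets differed by -0.02 and -0.0031. These differences run along with every group comparison given here. No test was run on these probe sets. The median log2 fold change of all 18132 genes was -0.09.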

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

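All tests of explanations in this part were chosen after the results they weigh were seen.

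The control probe set at the 5' end of ACTB was 0.68 higher on the log2 scale in the TCF19 siRNA arrays than in the control arrays, and the one at the 5' end of GAPDH 0.22 higher, in both arrays each, while the probe sets at the 3' ends differed by -0.02 and -0.0031. They stand out because they lie outside the gene comparison and were above the control arrays. Such a gap between 5' and 3' probe sets is the array's sign of a difference in RNA integrity or labelling, and it goes with the groups. Of 4305 probe sets with no or several gene symbols, 763 (17.7%) changed, 514 of them higher, against 20.1% of all 49293 probe sets tested.

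The arrays labelled TCF19 siRNA differ from each other, with TCF19 siRNA replicate 2 between the controls and replicate 1. A weaker response on the log2 scale in replicate 2 would keep the ratio of the log2 differences constant, but its median over bins of the difference in replicate 1 moved by 0.62, from 0.26 for the deepest falls to 0.89 for the largest rises. Random faults of the replicate 1 array would leave its low genes on either side of the controls in replicate 2. Of the 201 genes at least 4-fold lower in replicate 1 than in replicate 2, however, 99.0% lay below both controls in replicate 2. Among all 18132 genes, 7726 were below both controls in both TCF19 siRNA arrays. A fault that deepens low signals in replicate 1 would keep this order too, so the test cannot exclude it. A candidate explanation is that replicate 2 holds RNA like that of the controls: on the linear scale, the share of control-like RNA that explains each gene had a median of 36.2% (quartiles 28.8% and 44.5%) over 2946 genes at least 2-fold apart in replicate 1, and the medians of 6 bins, from falls over 16-fold to rises over 16-fold, lay within 3.96 percentage points. Whether such a share came from mixing of samples or from cells that did not respond stays open, since both give the same shares, and TCF19 itself gave a share of 10.7%.

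The second pattern is the size of the difference between the groups, with 40 genes over 64-fold lower and 4 over 64-fold higher in TCF19 siRNA replicate 1. A difference in labelling or hybridisation between the arrays stays open. Where the first probe set differed at least 4-fold, 94.1% of 1125 other probe sets of the same 492 genes differed in the same direction, but they read the same labelled target, and all 9 hybridisation controls were lower in both TCF19 siRNA arrays (median -1.03). The cells of the groups may differ in more than TCF19 siRNA, in gene copy number or origin. Neighbouring autosomal genes were put in windows of 50, or fewer (at least 20) at the end of a chromosome. Symbol families were thinned to 1 gene per window, and the windows were then redrawn, so a family can recur. The SD of the window medians was 2.59 times that of shuffled gene orders in TCF19 siRNA replicate 1 (0.18 against at most 0.08 in 1000 shuffles). It was 2.13 times in replicate 2, against 1.03 times for the difference between the controls. The medians of the 286 windows correlated at 0.93 between the TCF19 siRNA arrays, which are set against the same control mean. A response to TCF19 siRNA, the biological explanation that the design gives, could not be tested, because half-lives were not measured. The deepest fall, -9.17 for LUM in 24 h, allows a mean half-life of at most 2.62 h, which alone decides nothing. Regulation of whole chromosome regions was not tested and would also shift neighbours together.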

How the results depend on the processing

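TCF19 was lower under every alternative, with log2 fold changes from -0.95 to -0.73 over the leave-one-out fits and adjusted p from 1.81e-09 (trend and robust prior) to 0.153. It did not pass without control siRNA replicate 1 or 2. A lone array in a group is assumed to vary like the other group. The count of changed genes ran from 0 to 6663 over the leave-one-out fits (higher 0 to 3694, lower 0 to 2969), with limma calling 0 without either control array, where 4190 and 4279 genes had an unadjusted p under 0.05. It was 6753 with the intensity trend (3040 lower), 7103 with trend and robust prior (3274 lower) and 9921 of 49293 with every probe set tested on its own. The robust prior without trend, chosen after seeing the data, gave 4682. A shift to a common median left 1021 lower genes. At adjusted p under 0.10 there were 7024 genes, under 0.01 there were 329, at unadjusted p under 0.05 there were 7669, and with treat at 1.2-fold there were 1874. With the replicate block 3177 genes changed, 1002 of them lower, and the TCF19 adjusted p was 0.0323. The arrays were not taken as paired, because the labels do not say that a replicate number marks a shared culture or day. Same-numbered arrays deviated with a correlation of 0.02. With 1 deviation per gene in each group, this value cannot show whether they were paired. The block changed no call among the 40 lists reported. At least 1.5-fold apart without overlap, the leave-one-out fits gave 3706 to 5328 genes. Without overlap, 2223 genes were at least 2-fold apart, and 6933 at least 1.5-fold with the probe set of largest interquartile range. The 10 candidates gave 5 calls with the trend, 6 with trend and robust prior, 5 with the probe set of largest interquartile range, and 0 to 5 over the leave-one-out fits.

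Of the gene lists, 0 passed with an estimated correlation, also without TCF19 siRNA replicate 1 (chosen after seeing the data), 1 with fry and 16 with camera by ranks. With the trend 3 higher lists passed. The leave-one-out fits gave 11 to 21 lists, 3 to 5 higher and 7 to 17 lower. The trend ended the calls of glycolysis, acute phase proteins, RNA interference and cytosolic ribosomal proteins, and the probe sets of unshared sequence, chosen after seeing the data, those of gluconeogenesis and cytosolic ribosomal proteins. The probe set of largest interquartile range ended that of gluconeogenesis and added coagulation and complement. Some means near 0 changed sign. With the median shift, the NuRD mean was 0.0413 and the heat shock mean 0.0446, with the probe set of largest interquartile range 0.0823 and 0.0160. With unshared probe sets, RPS23 was at -0.0862, the TCA cycle at -0.0189, H3K4 methylation at -0.0238 and heat shock at 0.00788. Over the leave-one-out fits NuRD ran from -0.0396 to 0.00920, H3K4 methylation from -0.00445 to 0.0410 and heat shock from -0.0744 to 0.0507. The cause of these changes was not tested. Of 144 named genes, 24 lost their call with the block and 18 with the median shift. The filters on the genes of lowest level, quantile normalisation and cyclic loess were not run, because they need levels, and a robust prior was not run for gene lists, because camera does not offer it.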

Other observations

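The families and genes in this part were chosen after the data were examined. Families of genes that share a symbol stem, with at least 10 measured members each, gave 251 sets. Of these, 20 passed camera, 15 higher and 5 lower, and the families named were chosen after these results were seen. Among those of RNA processing and translation, 8 of 12 SRSF splicing factors rose and 0 fell (mean log2 fold change 0.65, camera adjusted p = 0.00965), as did 7 of 10 EXOSC genes of the RNA exosome (0.65, adjusted p = 0.00571), 7 of 11 UTP genes of ribosome assembly (0.75, adjusted p = 0.00571) and 21 of 51 EIF translation factor genes with 3 lower (0.32, adjusted p = 0.00342). Others of that kind did not pass: RPL (adjusted p = 0.158), RPS (0.257), EEF (0.268), RBM (0.191), PRPF (0.490), DDX (0.469), CNOT (0.794), SF (0.879) and LSM (0.0506). Of 492 ZNF zinc finger genes, 124 rose and 25 fell (0.31, adjusted p = 0.00291). The collagen family was lower by camera, with 6 of 44 falling, 1 rising and a median of -0.24 (mean -0.49, adjusted p = 0.00992), as was that of SERPINB protease inhibitors, with 4 of 12 falling, 0 rising and a median of -0.76 (mean -0.88, adjusted p = 0.0487). None of these families passed with an estimated correlation (adjusted p = 0.755). MAGE genes held 6 higher and 0 lower of 24, with a mean of 0.45 and a median of -0.14, and did not pass (adjusted p = 0.921).

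Olfactory receptor genes, which cells outside the nose seldom use, had a median log2 fold change of -0.14 over 341 genes, 8 of them lower and 1 higher, close to the -0.12 of the background probe sets. The same camera test called this family lower (adjusted p = 0.0418), and the KRTAP genes of hair keratin-associated proteins too (median -0.22 over 82 genes, adjusted p = 0.0166), and neither passed with an estimated correlation (adjusted p = 0.755 for both).

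Windows of neighbouring genes, ordered by the assembly GRCh38.p14, differed most in TCF19 siRNA replicate 1 from PAG1 to GDF6, where 27 of 50 genes were higher and 1 lower, with medians of 1.00 in TCF19 siRNA replicate 1 and 0.63 in replicate 2. From FHL5 to METTL24, 30 of 50 were higher and 1 lower (0.96 and 0.64), from KCNN3 to TSACC 1 was higher and 8 lower (-0.54 and -0.28), and from LGALS9 to GOSR1 0 were higher and 11 lower (-0.44 and -0.33).

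The liver protein transcripts named here ranged from deep falls to a large rise. SPP1, of the hepatocyte identity list, rose by 5.71 ± 0.20, and SERPINA1 had 0.39 ± 0.18 and did not pass. The log2 fold change was -0.11 ± 0.15 for the fibrinogen gene FGB, -0.16 ± 0.18 for TTR, -0.25 ± 0.12 for APOA1 and 0.05 ± 0.10 for APOB, which did not pass. The complement gene C3 was at -6.98 in TCF19 siRNA replicate 1 and at -1.14 in replicate 2, C1S at -5.42 and -1.40, and the urea cycle gene CPS1 at -5.41 and -1.43, and these did not pass either (adjusted p = 0.174, 0.118 and 0.114). Of the 108 genes in the lists of acute phase proteins, apolipoproteins, coagulation and hepatocyte identity, 13 changed between the groups, against 24.2% of all genes.

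The control arrays differed in some of the same 108 genes. The albumin gene ALB was 1.94 higher on the log2 scale in control siRNA replicate 2 than in replicate 1, in 3 of 3 probe sets, APOA2 1.22 higher, A2M 1.08 higher, TF 0.70 higher and AFP 0.53 higher. C3, C1S and CPS1 differed little between the control arrays (0.10, 0.17 and -0.09). The mean difference of the 108 genes was 0.11 and the median 0.06, with 69 of them higher in control siRNA replicate 2. The mean over all genes was 0.01, and the 95th percentile of the means of 10000 random lists of as many genes was 0.04. Random lists do not keep the correlation between related genes, and each side is a single array. No p-value is therefore given.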
